A study of Mus musculus with 6 samples.

How the data were processed

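PHF13, called SPOC1 in the library names, is a PHD finger protein that binds methylated histone H3. It was targeted by chromatin immunoprecipitation and sequencing (ChIP-seq) in testis of C57Bl/6 mice aged 5 weeks. Per the labels, there were 6 libraries: 3 SPOC1 ChIP libraries and 3 input libraries, numbered as replicates 1 to 3 and carrying the animal codes D707, D821 and E117. Both libraries of D707 are labelled wild type and both of E117 are labelled Phf13-/-. The input of D821 is labelled wild type and its ChIP is labelled Phf13-/-, so the labels differ within that animal. Genotype was therefore not used to form groups, and whether signal in a Phf13-/- library could serve as a control for the antibody was not analysed here. The regions are therefore not taken as sites of PHF13 binding.

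Per the submitters' processing notes, the tools were Bowtie2 2.2.2, SAMtools and HOMER 4.6, with the mouse build mm10; the notes as used here give no roles. The authors deposited 1 list of regions for the whole series, which per the file headers was written by HOMER's annotation program against mm10. Which libraries were pooled, which input was the control and which peak settings were used is not given in the sources used here. The list gives for each region its position, its length, the authors' score, the annotation class and repeat at the region's centre, the nearest gene and the signed distance to its transcription start site (TSS). It has 0 columns of values per library.

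The score is the authors' own value for each region, and its unit is not stated per the file headers. The score values lie on an even grid with a step of 0.2124: 100% of the scores under 1000 fell on it, within 0.005 for scores under 10 and within 0.05 for higher ones. Such a grid is what whole tag counts multiplied by 1 constant would give. If a step were 1 tag, the lowest score of 4.25 would be 20 tags (95% Poisson interval 12.2 to 30.9) and the median score 84 tags (67 to 104). The depth of each library is unknown, so no precision per library was computed. Because the score grows with region length, it was also divided by length (score per kb). Score was used only within the list: to describe, rank and filter regions, and to compare groups of regions with each other.

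Regions were counted by chromosome, annotation class and repeat, with Wilson 95% intervals, which cover counting error only. Chromosome spans ran from the first to the last gene or region. Protein-coding genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 names; the table has no strand, so both ends of a gene were treated alike. Genes on chromosomes 1-19 and X with a start below 3 Mb were left out as scaffold coordinates. Region lengths were placed at random within the same chromosome 100 times with bedtools 2.31.1 (shuffle, fixed seeds), and the observed count was divided by the random mean. Assembly gaps and sequence to which reads cannot be placed uniquely were not masked. The placement was tested on simulated data: uniform regions fell inside genes at 0.997 times the number that the length of the genes gives, and a removal of 50% of the regions in genes was recovered as 0.502. For 1 simulated set of uniform regions, the ratio to random placement, expected to be 1, was 1.01 inside genes and 1.07 at gene ends. An earlier form of the placement was not uniform; it was replaced after its values had been seen, and no bound of the tests that use it was changed.

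A promoter region was one within 1 kb of a TSS by the distance in the list. For 20 gene lists, Fisher's exact test (two-sided) compared the share of list members with a promoter region with that of all other protein-coding genes (21779 genes), with Benjamini-Hochberg adjustment over the lists. The lists covered undifferentiated spermatogonia, differentiating spermatogonia, meiotic prophase, spermiogenesis, the piRNA pathway, Sertoli cell markers, Leydig cell markers, peritubular, vascular and macrophage markers, Hox genes, ribosomal proteins, replication-dependent histones, writers and erasers of H3K4 methylation, H3K9 methylation and heterochromatin, Polycomb components, DNA damage response and repair, Phf genes, zinc finger genes (Zfp), olfactory receptors, vomeronasal receptors and keratins. In 200 simulations the olfactory receptor list, with 1105 members the longest, was set to 20 times the base rate. It was called in 100% of them, and no other list was called. No shorter list was raised, so the power for shorter lists was not measured. Genes were drawn independently, so false calls in clustered families were not covered. The gene numbers of 6007 of the 6033 genes named in the list matched the RefSeq table. Scores of promoter regions and all others were compared by a permutation test of the difference of median log2 score (100000 resamples, two-sided); regions are not replicates, so its p describes this list only. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

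The gene lists, the tests above, the alternatives named in this paragraph and the rule for named genes were fixed before the data were examined; tests and alternatives added later include the relation of gene density to region density, the window on X, the stretch on Y, the repeat families and the score per kb. The rule takes Phf13; the 12 genes with the highest score at a promoter region, leaving out predicted genes; up to 3 members of each list with a promoter region and the first 2 without one in alphabetical order; and the 5 regions with the highest score. Alternatives were the 50% and the 10% of the regions with the highest score, windows of 500 bp and 5 kb, the authors' promoter class, leaving out chromosome Y and unplaced contigs, all genes of the reference table, and autosomal genes. The 3 planned comparisons that need values per library were not run because the list has no column per library: ChIP against input at the regions, overlap of regions between replicates, and signal by labelled genotype.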

Results

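The data were 1 list of genomic regions from ChIP-seq of PHF13 (SPOC1) in mouse testis, in a series of 3 SPOC1 ChIP and 3 input libraries. Which of these libraries entered the list is not given in the sources used here. Of the ChIP libraries, 1 is labelled wild type and 2 are labelled Phf13-/-; of the inputs, 2 are labelled wild type and 1 Phf13-/-. The list held no value per library, so it has no replicate error, and the depth of each library is unknown. It could therefore not be asked whether ChIP exceeded input in each replicate, whether replicates shared regions, or whether the labelled genotypes differed. Intervals beside shares of regions are Wilson 95% intervals and cover counting error only. Since 2 of the 3 ChIP libraries are labelled Phf13-/-, whether the regions mark PHF13 itself could not be tested, and they are called regions and not binding sites. The list held 39096 regions in build mm10 that covered 56.2 Mb and did not overlap. Their median length was 789 bp (quartiles 500 and 1673 bp), and 31.2% were exactly 500 bp long. The authors' score had a median of 17.8 (quartiles 10.4 and 34) and ran from 4.25 to 33547.1.

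The first question was where in the genome the regions lay. Chromosome Y held 15782 regions, or 40.4% of the list (39.9 to 40.9%), the 19 autosomes together held 19819 (50.7%), and X held 3211 (8.21%). Unplaced contigs held 284. By covered length, Y held 30.1 Mb, which was 53.5% of all covered base pairs, and 32.8% of the summed score. The autosomes carried 8.11 ± 1.15 regions per Mb (SD, n = 19), from 5.27 on chromosome 11 to 9.94 on chromosome 14. X carried 19.2 regions per Mb, 2.36 times the autosomal mean, and Y carried 174 per Mb, 21.5 times that mean. X and Y each lay above all 19 autosomes; for 1 chromosome against 19, the smallest one-sided exact p is 0.05. On X, 702 regions started between 25 and 35 Mb, a window chosen after the data were seen, and the rest of X carried 15.9 regions per Mb. The Y share moved with the measure: it was 28.9% among the 10% of the regions with the highest score and 2.88% among the 50% with the higher score per kb, an alternative chosen after the data were seen.

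**Figure D1:**
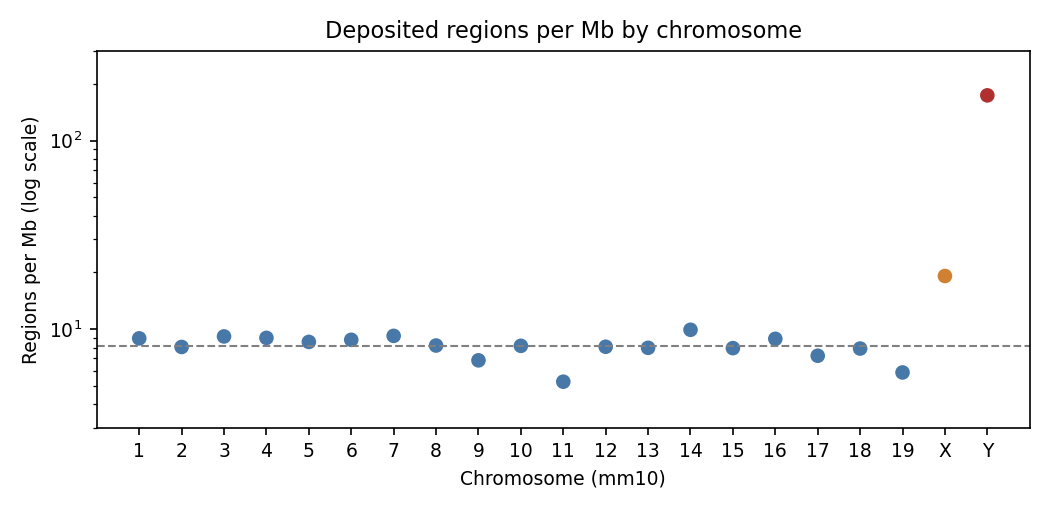
Regions per Mb on each chromosome of mm10, on a log scale; each point is 1 chromosome and the dashed line is the mean of the 19 autosomes (8.11). X (19.2) and Y (174) lie above every autosome.

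Along Y the regions were spread unevenly. From Zfy1 to Sry (725207 to 2663658), the stretch with the single-copy genes Ddx3y, Kdm5d, Uty, Eif2s3y and Usp9y, 55 regions lay in 1.94 Mb, or 28.4 per Mb (95% Poisson interval 21.4 to 36.9), and they covered 2.59% of it. The rest of Y carried 177 regions per Mb, which covered 33.8% of it. Most regions of the stretch, 92.7%, were centred on a LINE or LTR element, against 42.9% on the rest of Y. The score per kb went the other way, with a median of 23.5 in the stretch and 12.7 on the rest of Y. The genes most often nearest to a Y region were the predicted genes Gm20736 (2487 regions), Gm20871 (2012) and Gm20738 (1968). Among the multicopy genes expressed in spermatids, Sly was nearest to 522 regions, Ssty1 to 391 and Ssty2 to 351. The genes of the Zfy1 to Sry stretch were also counted over all of Y, so their counts include regions outside the stretch. Usp9y was nearest to 23 regions, Zfy2 to 17, Zfy1 to 16, Eif2s3y to 2 and Uty to 1. Ddx3y, Kdm5d and the sex-determining gene Sry were nearest to 0. The stretch and these genes were chosen after the list was seen.

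**Figure D2:**
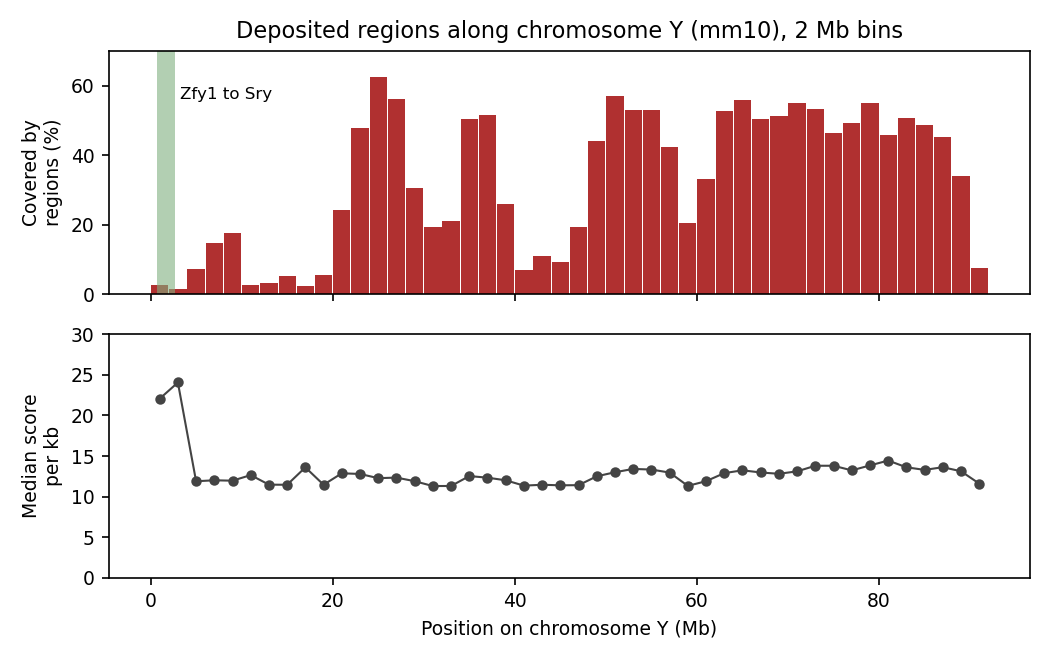
Position on chromosome Y (Mb, mm10) in bins of 2 Mb: the upper panel gives the percent of each bin covered by regions, and the lower panel the median authors' score per kb. The green band marks Zfy1 to Sry, where 2.59% was covered and the median score per kb was 23.5, against 33.8% and 12.7 on the rest of Y.

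Over the 19 autosomes, chromosomes with more protein-coding genes per Mb carried fewer regions per Mb by Pearson's r, -0.532 (permutation p = 0.0187). Spearman's rho was -0.319 (permutation p = 0.184). Without chromosomes 11 and 7, the farthest from the median in gene density, r was -0.69 over 17 autosomes (permutation p = 0.00226). Both coefficients belong to 1 relation, which was chosen after the data were seen, and no others of this kind were computed.

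Regions were mostly centred on transposable elements, above all young LINE-1 (L1) elements, which are retrotransposons that copy themselves through RNA. LINE elements lay at the centre of 20640 regions (52.8%, 52.3 to 53.3%) and LTR elements, which derive from retroviruses, at 6986 (17.9%). No repeat was named at the centre of 8285 (21.2%), called regions without a repeat, and simple repeats lay at 1642 (4.2%). At the named genes, all regions of the authors' promoter class had none named, so a repeat at such regions may go unreported. On the autosomes LINE elements made up 72.6% of the regions and LTR elements 17.9%, and 2.99% had no repeat at the centre. X was close to the autosomes for LINE elements, at 72.8%, and had 13.3% at LTR elements. On Y only 24.3% were at LINE elements, 18.8% at LTR elements, and 46.1% had no repeat. The LINE share was thus 72.6% without Y and the unplaced contigs.

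The families L1Md_T and L1Md_A together accounted for 64.7% of the autosomal regions (64.1 to 65.4%), 53.3% of those on X and 4.85% of those on Y. The autosomes held 7687 regions at L1Md_T and 5139 at L1Md_A, with medians of 29.5 and 29.0 for the score per kb. Intracisternal A particles (IAP), endogenous retroviruses that are still mobile in mice, accounted for 9.03% of the autosomal regions, with 1770 regions at IAPEz-int. MERVL-int and its long terminal repeat MT2_Mm, a retrovirus active in the early embryo, accounted for 4.3%. On the autosomes the median score per kb was 29.0 at LINE and 30.7 at LTR elements, against 12.7 at simple repeats and 13.5 where there was no repeat. On Y it was 13.2 at LINE elements, 12.5 at LTR elements and 12.6 without a repeat. Within these classes on Y it was 18.1 at L1Md_T, 22.2 at L1Md_A and 13.4 over all IAP elements. Among simple repeats, the tetranucleotides TAGA and TCTA held 476 autosomal regions and the trinucleotides GAA and TTC held 263. The families and the score per kb were chosen after the data were seen. The share of each element in the genome was not analysed here, so these shares are not enrichments.

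**Figure D3:**
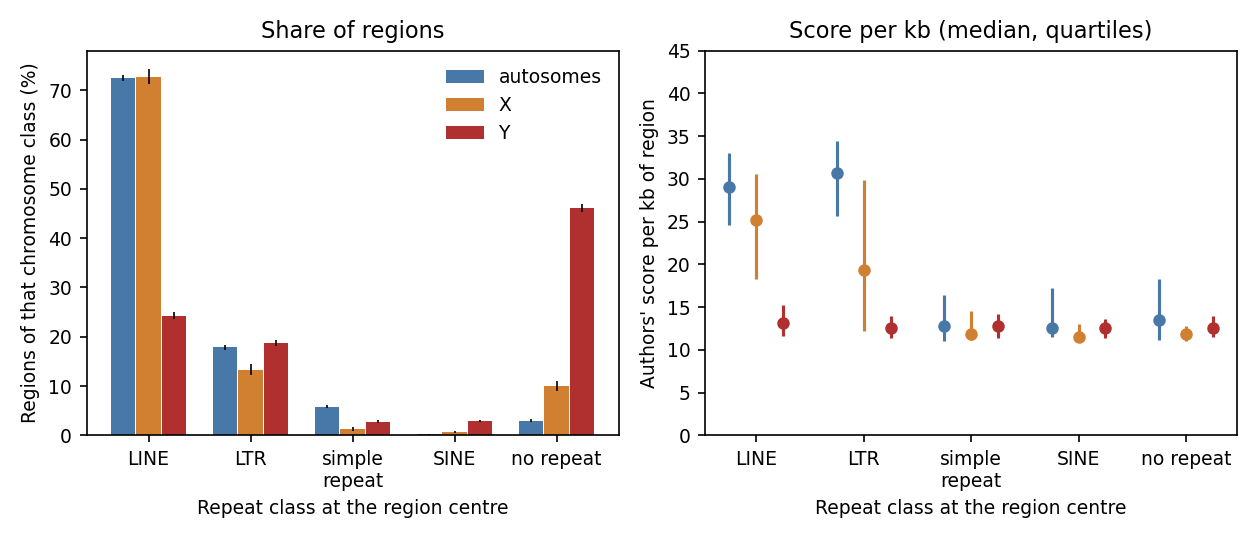
Left, percent of the regions of the autosomes, X and Y by the repeat class at the region's centre, with Wilson 95% intervals as bars. Right, median authors' score per kb with quartiles as bars. LINE elements lead on the autosomes (72.6%) and X (72.8%) and regions without a repeat on Y (46.1%), and the autosomal LINE and LTR medians (29.0 and 30.7) stand above those of simple repeats, SINE elements and regions without a repeat.

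The highest scores belonged to the major satellite (GSAT_MM), the tandem repeat of mouse pericentromeres. All 5 of the regions with the highest score were intergenic and centred on it. The first lay on an unplaced contig (68441 to 114438, score 33547.1). The second lay on chromosome 9 (3000149 to 3038544, score 28376.9). The next was on chromosome 14 (19415608 to 19419869, score 3334), and the last pair was on chromosome 2 (98661878 to 98665462, score 1162, and 98665973 to 98667638, score 1140). The first 2 of these held 5.04% of the summed score of the list. In all, 11 regions were centred on the major satellite, with a median score per kb of 597. The list has no value for input, and copy number was not analysed here. Whether input is also high at these regions could not be asked, so their scores are not taken as the strongest enrichment.

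Genes and their ends held few regions. By the authors' annotation 85.9% of the regions were intergenic (85.5 to 86.2%), 13.3% intronic, 0.174% at a transcription termination site, 0.11% at a promoter and 0.064% in other exons. The median distance to a TSS was 179 kb, and 63.2% lay farther than 100 kb from one. These values pool all chromosomes, and Y held 40.4% of the regions. Without Y and unplaced contigs the intergenic share was 78.6%. Within 1 kb of a TSS there were 67 regions (0.171%, 0.135 to 0.218%), of which 42 were on autosomes, 4 on X, 20 on Y and 1 on an unplaced contig. On the autosomes and X, 22.5% of the centres fell inside a protein-coding gene, against 38.7% on average in 100 random placements, a ratio of 0.581 (0.566 to 0.595 over the placements). Within 1 kb of either end of such a gene lay 0.486% of the centres, against 2.92% at random, a ratio of 0.166 (0.152 to 0.186). None of the 100 placements gave counts as low. With Y included, the ratios were 0.592 inside genes and 0.32 at gene ends. On Y itself they were 0.827 (0.724 to 0.959) and 1.01 (0.795 to 1.22), and 56 of the 100 placements were at or below the observed count at gene ends.

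**Figure D4:**
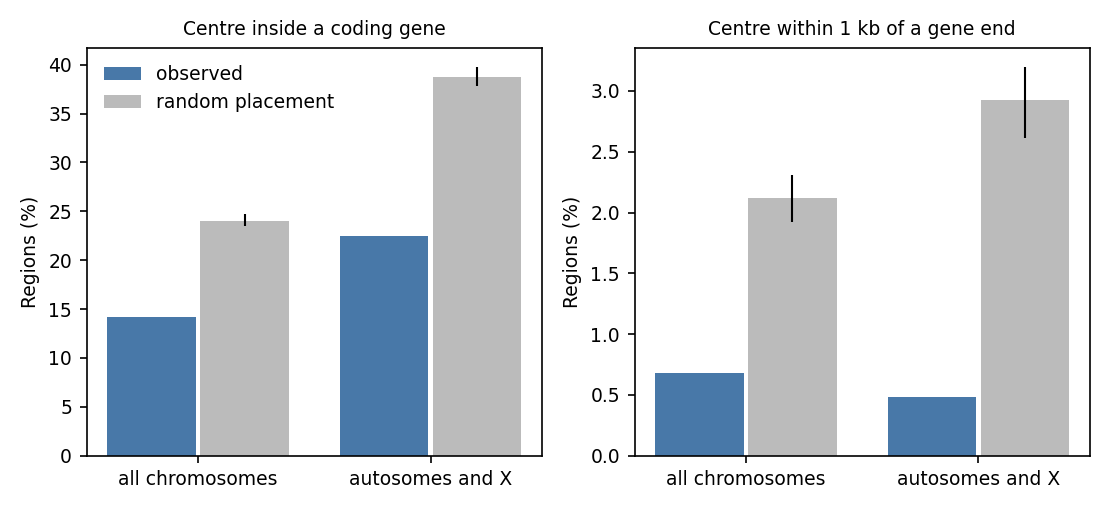
Percent of region centres inside a protein-coding gene (left) and within 1 kb of either end of one (right), for all chromosomes and for the autosomes and X; bars give the observed share and the mean of 100 random placements, with their lowest and highest as lines. On the autosomes and X the observed 22.5% and 0.486% lie below the random 38.7% and 2.92%.

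The next question was which genes had a region at their promoter. There were 51 protein-coding genes with a region within 1 kb of the TSS, 0.234% of 21779. Vomeronasal receptors, the pheromone receptors of the vomeronasal organ, were the 1 of 20 gene lists that passed the test: 6 of 350 members (1.71%) had a promoter region, against 0.21% of other genes (Fisher's exact test, two-sided, p = 0.000162, adjusted p = 0.00323). All 6 lay on chromosome 7, and neighbouring members of a cluster are not independent. The call ended in the 50% of the regions with the higher score, where no list passed, since the 6 scores ran from 5.31 to 12.5. The examples were Vmn1r155 (21993452 to 21994514, score 12.5), Vmn1r107 (23216095 to 23216595, 8.07) and Gm8653, named Vmn1r251 in the reference (22201262 to 22201887, 6.58). Vmn1r1 and Vmn1r10 had none. Olfactory receptors had 4 members of 1105 (0.362%, Fisher's exact test, adjusted p = 1), among them Olfr8 (score 28.5), Olfr368 (8.28) and Olfr119 (6.37), while Olfr1 and Olfr10 had none. With a window of 5 kb they had 50 members (4.52%, against 1.68% of other genes, Fisher's exact test, adjusted p = 4.13e-08), and vomeronasal receptors had 43 (12.3%). Olfactory receptor genes also lie in clusters, so their members are not independent and that p-value is too small. Within 10 kb of the gene body olfactory receptors did not pass (15.6% against 16.7%, Fisher's exact test, adjusted p = 0.803). Zinc finger genes had 2 of 394, Zfp354c (score 13.6) and Zfp40 (11.7), with adjusted p = 1 by Fisher's exact test, while Zfp1 and Zfp101 had none.

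The other 17 lists had 0 members with a promoter region. They were the 2 lists of spermatogonia, meiotic prophase, spermiogenesis, the piRNA pathway, the Sertoli, Leydig and peritubular, vascular and macrophage markers, Hox genes, ribosomal proteins, replication-dependent histones, H3K4 methylation, H3K9 methylation and heterochromatin, Polycomb, DNA damage response, Phf genes and keratins. Together they held 522 members, of which 1.22 would have had a promoter region at the overall rate. A count of 0 among 522 allows a share of up to 0.575%, which is above the overall 0.234%, so a lower share than in other genes was not detectable. For ribosomal proteins, with 80 members the longest of these lists, 0.187 members would have been found at the overall rate.

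Phf13 itself, the gene of the immunoprecipitated protein, had no promoter region. The gene lies on chromosome 4 (151989631 to 151996179), and the nearest region was 819 kb away (152814920 to 152815420, score 8.49), at a (TCTA)n repeat. With predicted genes left out, the highest score at a promoter belonged to Fut8, which adds core fucose to glycoproteins (chromosome 12, 77408433 to 77410682, score 68.6). Next came Bod1, which acts in chromosome attachment to the spindle (chromosome 11, 31670985 to 31671485, 45.7), in an intron and at a (TAGA)n repeat. Ssty2 on Y (22510033 to 22512825) had 39.1 and Bckdhb, a subunit of the branched-chain keto acid dehydrogenase (chromosome 9, 83947915 to 83949009), had 33.6. Olfr8 (chromosome 10, 78953911 to 78954675) had 28.5, the lectin gene Cd209c (chromosome 8, 3947020 to 3947793) 22.5 and the bitter taste receptor Tas2r134 (chromosome 2, 51626496 to 51627121) 19.7. Tex28 on X (74167265 to 74167891) had 17.4, in an intron at an L1Md_A element. The remaining 4 were Speer8-ps1 (score 15.9), Sly (15.1), Ccdc67 (14.7, named Deup1 in the reference) and Cpne1 (13.6). Ssty2, Sly, the vomeronasal and olfactory receptors and Speer8-ps1 belong to families of similar copies, where the placement of reads among copies is uncertain.

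Regions at promoters scored lower than the others in this list. The median score was 10.6 at the 67 promoter regions and 17.8 at the other 39029, a log2 difference of -0.75 (two-sided permutation p = 0.00011). Promoter regions were also shorter, with a median of 500 bp against 789 bp. By score per kb the medians were 13.9 and 19.1. The other regions include many at LINE and LTR elements, with autosomal medians of 29.0 and 30.7 per kb, while autosomal regions without a repeat had 13.5. Whether promoter regions score lower than other regions off such elements was not tested. Without Y and unplaced contigs the difference was larger, -1.22 (two-sided permutation p = 1e-05, the smallest that the resamples can give). With a window of 500 bp it was -1.44 (two-sided permutation p = 5e-05). With only Y left out, the medians were 8.28 at promoter regions and 19.1 at the others. Among the 50% of the regions with the higher score the difference was 0.12 (two-sided permutation p = 0.71), where the score that was tested also selected the regions. The score is the authors' own, and the regions are not replicates.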

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

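The Y share by covered base pairs and by score per kb, the LINE share without Y only, the lists at 10 kb, with and without matching on gene length, and the promoter score per kb were chosen after seeing the data. The number of regions was 19548 and 3909 in the 50% and 10% with the highest score, by construction, and 23030 without Y and unplaced contigs. In the same order, the intergenic share was 84.5%, 81.4% and 78.6%, and the LINE share 61.6%, 70.8% and 72.6% (72.1% without Y only). The Y share was 35.8% and 28.9% in the 50% and 10% with the highest score, 2.88% in the 50% with the higher score per kb, and 53.5% by covered base pairs. X carried 1.72 and 2.03 times the autosomal mean in the 50% and 10% with the highest score. The share within 1 kb of a TSS was 0.0819% and 0.0256% there, 0.0716% at 500 bp, 1.68% at 5 kb and 0.11% by the authors' promoter class. The ratio to random placement stayed below 1 in each alternative, at 0.581 to 0.676 inside genes and, at gene ends, 0.166 without Y, 0.16 in the upper 50% and 0.0444 in the upper 10%. The number of gene lists called was 2 at 5 kb, 0 in the 50% with the higher score and 4 within 10 kb of the gene body; against genes of the same length it was also 4, with Zfp genes in place of Hox genes. The vomeronasal call held at 500 bp, with all genes and with autosomal genes (unadjusted p from 3.38e-06 to 0.000456). The log2 score difference at promoters reversed to 0.12 in the 50% with the higher score, which removes low scores from both sides; it was -1.44 to -0.33 in the other alternatives. For the remaining shifts the cause was not tested. No paired analysis was possible because the list has no column per library. For that reason the following were not run: the filter on high input, and, for ChIP against input and the overlap between replicates, every alternative (normalization, count model, low-count filter, replicate block, pseudocount, overlap rule, score cutoff and leaving out each replicate). The unknown depth per library limits the list most at its weak end, where a region may rest on about 20 tags if a score step is 1 tag.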

Other observations

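Chosen after the results were seen were the gene lists within 10 kb, with their test against genes of the same length, the dense windows, the test of L1Md_T on Y, the comparison of 500 bp regions, the tests of covered base pairs and of the Zfy1 to Sry stretch on Y, and the test of gene ends on the autosomes and X alone; the other tests of the patterns were set before. Counting any region centre within 10 kb of a gene body, 3620 protein-coding genes (16.6%) had a region nearby. Vomeronasal receptors had 113 of 350 members (32.3%, Fisher's exact test, adjusted p = 8.81e-12), against 16.4% of other genes. Ribosomal protein genes had 0 of 80 (Fisher's exact test, adjusted p = 1.01e-05), replication-dependent histone genes 3 of 66 (4.55%, adjusted p = 0.0228) and Hox genes 0 of 39 (adjusted p = 0.0116). That test takes no account of gene length. Against genes of the same length, an exact test gave adjusted p = 1.94e-13 for vomeronasal receptors (15.7% expected), 0.00726 for ribosomal proteins (9.37% expected) and 0.0168 for histones (17.9% expected). The call for Hox genes ended (exact test, adjusted p = 0.149, 8.9% expected), and Zfp genes, with 71 of 394 (18%, 13.2% expected), passed at adjusted p = 0.0284 after 0.844 by Fisher's test. The remaining 15 lists passed neither test; meiotic prophase had 8 of 40, spermiogenesis 4 of 33, the piRNA pathway 2 of 19 and olfactory receptors 172 of 1105. Vomeronasal, olfactory, Hox, histone and many Zfp genes lie in clusters, so their members are not independent and these p-values are too small.

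The 2478 windows of 1 Mb on the autosomes and X that held any region held a median of 8. The densest was on X from 28 to 29 Mb, with 133 regions, followed by 30 to 31 Mb (112) and 27 to 28 Mb (102). X from 4 to 5 Mb, where Btbd35f3 lies, held 78. On the autosomes the densest were chromosome 2 from 175 to 176 Mb, where Zfp968 lies (56 regions), chromosome 5 from 11 to 12 Mb, where Speer1 lies (54), and chromosome 5 from 94 to 95 Mb, where Pramel37 lies (51). The genes are named only to place the windows, and no gene family was tested for enrichment in them. In these windows the median score per kb was 11.9 to 16.2, near the 12.7 of Y and below the autosomal 28.7.

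The share of regions on Y (40.4%) was the first pattern weighed. If Y signal were only cut into more pieces than elsewhere, the Y share of covered base pairs would lie below its share of regions, but it was higher, 53.5%, which argues against this. For calls near the threshold, Y kept 28.9% of the 10% with the highest score, which met the bound set beforehand against this explanation. Yet the score grows with length, which that bound did not consider. By score per kb, a split chosen after the data were seen, Y held 2.88% of the upper 50%, so calls near the threshold stay open. Reads shared between near-identical copies may also contribute, and cannot be told apart from a true excess. The Zfy1 to Sry stretch carried 28.4 regions per Mb (95% Poisson interval 21.4 to 36.9), 3.5 times the autosomal mean. This was far below the 177 of the rest of Y, and it met neither bound. The limit set for shared reads, a multiple of the autosomal mean, lay inside that interval, so it was missed only within counting error. No biological explanation was tested, since the list has no value per library or group, and copy number in input was not analysed here.

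The even score per kb over copies of young L1 elements was the second; the upper quartile of autosomal L1Md_T regions was 1.32 times the lower. If reads were spread over near-identical copies wherever they lie, X and Y, each present once per pair of autosomes, would not fall below the autosomes. On Y the L1Md_T median was 0.614 times the autosomal one (bootstrap 95% interval 0.589 to 0.656), and 0.634 among regions of 500 bp, both under the bound of 0.75. L1Md_A was at 0.766, or 0.724 (0.692 to 0.785) at 500 bp, and L1Md_F2 at 0.536. IAPEz-int was at 0.858 (0.738 to 0.96), or 0.805 (0.725 to 1.04) at 500 bp. The 5 MERVL-int regions on Y had a median of 28.2 per kb against 32.8. The median score per kb on Y was 18.1 at L1Md_T (quartiles 14.25 and 24.86), 22.2 at L1Md_A and 27.6 at IAPEz-int. Without a repeat it was 12.6 (quartiles 11.46 and 13.91), over all LINE elements 13.2 and at L1Md_F2 13.3. Regions at L1Md_T on Y thus mostly scored above those without a repeat. How much of such a score reflects the element at the centre is unknown, so the question stays open for Y. For X the question also stays open. The L1Md_T median was 0.923 times the autosomal one (0.902 to 0.945), which met the bound set beforehand for reads spread over copies. The ratio was 0.952 for L1Md_A, 0.97 for IAPEz-int, 1.01 for MERVL-int and 0.703 for L1Md_F2. Among L1Md_T regions of 500 bp, a comparison added after the results were seen, it was 0.821 (0.784 to 0.858), which met neither bound. A threshold that drops weak copies could raise these ratios and was not tested, and no biological explanation was tested.

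Few regions near gene ends was the third. A preference for gene-poor sequence alone was set to give the same ratio to random placement at gene ends as inside genes. On the autosomes and X the ratio at gene ends was 0.166 and inside genes 0.581, which met the bound against it. The bound assumes that genes in gene-poor sequence are as long as elsewhere. Neither gene length nor local gene density was matched in the placement, so the values cannot decide this. With Y included the ratio was 0.32 against 0.592, which met neither bound, so that version stays open as well. On Y gene ends were as frequent as at random. A score threshold remains a candidate explanation: the share within 1 kb of a TSS was 0.261% (0.199 to 0.343%) in the lower 50% of the regions by score and 0.0819% (0.0504 to 0.133%) in the upper 50%, so weaker regions at promoters may lie below it. These shares concern TSS and not both gene ends, and they include Y, which held 20 of the 67 promoter regions. They restate the lower promoter scores given above and are not separate support. How often the repeats that carry regions lie at gene ends was not analysed here, and no biological explanation was tested.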
